A study of Homo sapiens with 35 samples.

How the data were processed

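Polyadenylated RNA of H9 and HUES4 cells was sequenced with NEBNext Ultra II libraries, per the labels' protocols. They give 5 days of culture for all types together. The deposited file holds counts per gene, for 58302 Ensembl genes in 35 libraries. Per the submitters' processing notes, the authors aligned reads with STAR to hg38. The counting program, the gene annotation and the use of strand are not given in the sources used here, so a gene and a transcript from the other strand at the same place may share counts, and so may near-identical family members (LEFTY1 and LEFTY2, metallothioneins, histones). No row was other than a gene. Of the IDs, 58039 are in GENCODE v29, which gave symbols and coordinates on GRCh38, and 263 are not. In 46245 genes at least 1 library has a count.

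All 35 columns were matched to the labels, 31 to a sample and 4 (RSeT PrE) to their group only, since the names of the 4 columns carry 2 sets of numbers that the labels do not tie to samples. In order, the groups and their totals are t2iLGo nES (n = 3, 21.32 to 23.71 M counts, M for mega), t2iLGo PrE (3, 26.26 to 29.61 M, as for all that follow), h2iL nES (3, 25.85 to 28.96), h2iL PrE (3, 28.13 to 31.21), H9 pES (2, 19.99 to 23.00), HUES4 pES (2, 22.53 to 22.79), HUES4 ADE (2, 25.30 to 28.18), H9 ADE (2, 21.78 to 27.54), RSeT nES (2, 20.59 to 24.88), RSeT PrE (4, 20.93 to 22.88), t2iLGo nEnd (3, 25.32 to 28.73), H9 DE (3, 22.84 to 28.19) and RSeT nEnd (3, 20.58 to 21.69). At these depths 1 count is about 0.03 to 0.05 CPM. No 2 libraries of a group are copies, the closest differing 2.21 times more than counting noise would.

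The tests, the settings, the lists and the rule for naming genes were written down before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, 1 coefficient per group over all 35 libraries (22 residual degrees of freedom) and quasi-likelihood F-tests, two-sided, with Benjamini-Hochberg adjustment over the 23980 genes tested. The common dispersion was 0.0204. A gene is called at an adjusted p under 0.05 and a change of at least 2-fold. There are 16 comparisons of 2 groups and 4 differences between such comparisons. CPM are on library totals times their TMM factor (0.819 to 1.22). Where a group has no counts, "at least" gives the fold to a floor of 3 counts over that group, and genes with 1 to 3 counts are given as CPM alone.

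Gene lists, 23 in number and fixed beforehand, cover naive, conventional and core pluripotency, shared, extra-embryonic and definitive endoderm, primitive streak and mesoderm, basement membrane, secreted plasma proteins, WNT, Nodal and Activin, LIF and STAT3, and FGF and ERK targets, DNA methylation, imprinted genes, 5 other lineages (trophectoderm and amnion, mesenchyme and fibroblast, neural ectoderm, hepatic and gut endoderm, haematopoietic and endothelial), proliferation, stress and p53, and mitochondrial transcripts. They were tested with camera (limma 3.58.1, preset correlation 0.01), again with a correlation estimated from the data, and with fry. Of 460 pairs of list and comparison camera called 200, of which 36 hold with an estimated correlation. Where the latter lost the call its p is printed. Counts adjusted over the list alone are the same as those over all genes in 410 pairs and are printed where they differ. Named genes are chosen among the 4 called members of each list described with the largest change, a fixed panel of 22 markers, called or not and not all printed each time, and the 5 largest changes each way with a mean of at least 10 CPM in the higher group and no overlap between groups. For differences between comparisons they are the 5 largest each way and called list members. Genes whose values would tell a person's sex are not reported, and 1 other gene that the rule selects is not reported here.

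In simulated counts 200 genes were changed per run, 100 by log2 1.5 and 100 by log2 3. For h2iL against t2iLGo naive cells the fit recovered 95 and 100 (23528 genes, 4 false calls). For t2iLGo PrE against naive cells it recovered 96 and 100 (23485 genes, 8 false). H9 ADE against conventional cells gave 89 and 100 (23487 genes, 0 false). The wider changes called in the data were not tested. Alternatives tried were RLE scaling, DESeq2 1.42.0, no filter, a filter of 1 CPM in every sample of a group, adjusted p under 0.01, no minimum fold, only the groups compared, each library left out in turn, replicate number as a block, and the RSeT PrE libraries summed in 2 ways. Library totals alone for scaling and either RSeT PrE set alone were added after seeing the data. Reads were not available, so alignment and counting were not repeated.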

Results

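The libraries measure polyadenylated RNA of human embryonic stem cells and of endoderm grown from them, as 35 libraries in 13 groups of 2 to 4. H9 and HUES4 are established human embryonic stem cell lines. Conventional cells (pES) grew with FGF2. Naive cells (nES) grew in 3 media, t2iLGo, h2iL and RSeT, where t2iLGo and h2iL hold LIF and the GSK3 inhibitor CHIR99021 with other inhibitors and RSeT is a commercial medium. The labels call PrE and nEnd extra-embryonic endoderm, with LIF, CHIR99021 and Activin A, and ADE and DE endoderm, with either the same 3 factors or another protocol, without saying which group had which. The H9 DE columns carry the letters RACL, and the conventional columns MEF in H9 and DEF in HUES4, none of which the labels explain. The mark New stands on 2 of the 4 RSeT PrE columns and all 3 RSeT nEnd columns. Totals run from 19.99 to 31.21 M (mega) counts per library, and 23980 genes were tested. Values in parentheses are mean CPM (scaled to TMM-adjusted totals) ± SD, first group named against the second. "Rose", "fell", "higher" and "lower" mark called genes (edgeR adjusted p under 0.05, change of at least 2-fold). List p-values are from camera. The labels do not say if replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. That spread is per gene over all 13 groups, not the 2 compared.

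The comparisons ask 6 questions: how naive cells differ from conventional cells, how the naive media differ, what changes when naive cells become PrE, how nEnd differs from PrE, what changes when conventional cells become ADE or DE, and how PrE and nEnd differ from ADE and DE. Replicates of a group correlate at a mean of 0.985 or above on log2 CPM. The naive cells of t2iLGo and h2iL lie close together (mean r = 0.994), and so do their PrE cells (mean r = 0.994). RSeT PrE lies nearer H9 DE (mean r = 0.964) than t2iLGo PrE (mean r = 0.916). The first 3 principal components hold 34.1, 27.4 and 11.9 percent of the variance.

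**Figure D1:**
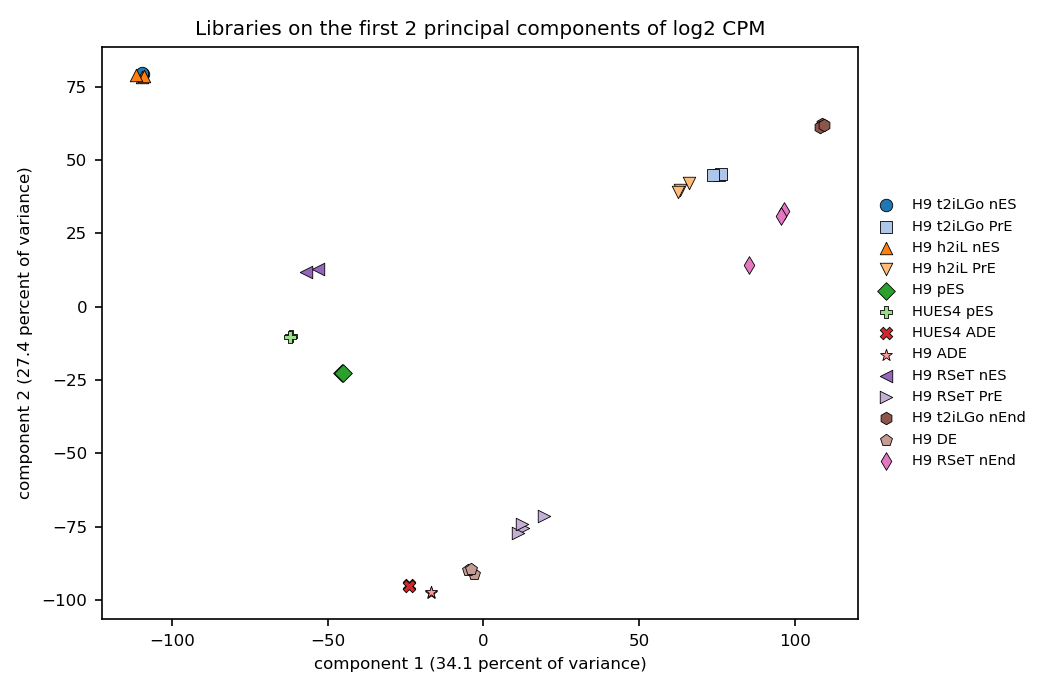
The 35 libraries on the first 2 principal components of log2 CPM, coloured by group. RSeT PrE lies by DE and ADE, and the PrE of the other 2 naive media lies by nEnd.

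Genes that recur below have these places on GRCh38 (GENCODE v29). KLF17 (ENSG00000171872) spans chr1:44118850-44135140, DPPA5 (ENSG00000203909) chr6:73353062-73354295 and NANOG (ENSG00000111704) chr12:7787794-7799141. PDGFRA (ENSG00000134853) spans chr4:54229097-54298247, COL4A1 (ENSG00000187498) chr13:110148963-110307233, SOX17 (ENSG00000164736) chr8:54457935-54460888 and CER1 (ENSG00000147869) chr9:14719724-14722717. Counts are of whole genes, so exons and transcripts are not told apart.

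In t2iLGo naive cells against H9 conventional cells (n = 3 and 2), 4244 genes were higher and 5611 lower, and with scaling by library totals 3446 and 6520. Of the naive list, 20 of 20 were higher (camera adjusted p = 6.76e-31), among them KLF17 (44.8±0.36 against 0, at least 741-fold), a zinc finger factor of the pre-implantation epiblast, DNMT3L (1223±36 against 0.528±0.32), a cofactor of de novo DNA methylation, and DPPA3 (227±3.4 against 0.175±0.13) and DPPA5 (501±16 against 2.32±0.29), both genes of the germline and early embryo. In the conventional list, 20 of 20 were lower (camera adjusted p = 4.43e-22), with THY1 (0.107±0.097 against 168±0.049), a surface protein of conventional cells, FZD7 (1.89±0.31 against 539±5.9), a WNT receptor, and the factor ZIC2 (0.821±0.13 against 170.1±4.1). NANOG (155±2.6 against 35.2±0.13) was higher, SOX2 (149±3.3 against 352±0.90) lower and POU5F1 (985±24 against 851±11) not called, all 3 being core pluripotency factors. The FGF and ERK feedback genes were lower (15 of 16 lower, camera adjusted p = 4.45e-11, adjusted p = 0.0516 with an estimated correlation), with the ERK phosphatase DUSP6 (0.197±0.12 against 33.8±3.7, log2 fold change -7.41±0.49 SE, adjusted p = 8.41e-14), the ERK inhibitor SPRY4 (0.0590±0.024 against 117±2.6) and EGR1 (0.209±0.069 against 92.96±4.6). Within the LIF and STAT3 list, 8 were higher and 3 were lower of 13 (camera adjusted p = 0.0209, adjusted p = 0.0516 with an estimated correlation), with KLF4 (260.4±5.1 against 7.57±1.7), TFCP2L1 (234±12 against 12.1±2.0) and the LIF co-receptor IL6ST (109±3.0 against 11.05±0.57). The de novo methyltransferase DNMT3B (352±8.7 against 1874±10.5) was lower. Of the DNA methylation list, 3 were higher and 2 were lower of 10 (camera adjusted p = 0.926, with the median, mean and test not of one sign). Endoderm factors were called in part, HNF4A (21.4±1.9 against 0.113±0.16) and GATA4 (3.32±0.45 against 0.407±0.097) higher, while the receptor PDGFRA (0.462±0.18 against 5.43±0.95) was lower. Imprinted transcripts MEG3 (844±57 against 0.707±0.040) and PEG3 (34.8±0.87 against 0.167±0.13) were higher. Stress genes TRIB3 (395±4.0 against 9.84±0.21) and DDIT3 (52.4±3.0 against 1.82±0.66), which respond to amino acid and endoplasmic reticulum stress, were higher. At the top of the table stood the zinc finger gene ZNF676 (97.6±3.7 against 0, at least 1615-fold) and at the bottom the chemokine CXCL5 (0 against 62.4±5.0). Mitochondrial transcripts made 3.07±0.08 percent of counts against 6.48±1.06, and of that list 6 of 13 were lower (camera adjusted p = 0.0470, adjusted p = 0.768 with an estimated correlation), or 9 with scaling by library totals.

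The h2iL naive cells against the same conventional cells (n = 3 and 2) gave 4036 genes higher and 5712 lower, and with scaling by library totals 3360 and 6527. All members of the naive list moved as in t2iLGo (20 of 20 higher, camera adjusted p = 3.83e-32), with KLF17 (49.04±5.2 against 0, at least 812-fold), DNMT3L (1145±34 against 0.528±0.32), DPPA3 (283±12 against 0.175±0.13), DPPA5 (649±33 against 2.32±0.29) and ZNF729 (246±22 against 0.0998±0.019), a zinc finger gene marking naive cells. For the conventional list, 20 of 20 were lower (camera adjusted p = 1.82e-21), with PTPRZ1 (0.247±0.15 against 307±14), THY1 (0.366±0.083 against 168±0.049), ZIC2 (0.917±0.10 against 170.1±4.1) and CYTL1 (0 against 3.98±0.18, at least 109.5-fold). Of the core factors NANOG (171±2.9 against 35.2±0.13) was higher, and POU5F1 (888±32 against 851±11) and SOX2 (183±12 against 352±0.90) were not called, the latter being called lower with scaling by library totals (log2 fold change -1.15). Among FGF and ERK genes, 14 of 16 were lower (camera adjusted p = 1.83e-09, adjusted p = 0.0849 with an estimated correlation), with SPRY4 (0.294±0.090 against 117±2.6), DUSP6 (0.122±0.023 against 33.8±3.7), DUSP4 (0.0851±0.023 against 8.74±1.2) and ETV1 (1.56±0.52 against 72.7±5.9), an ETS factor. LIF genes gave 8 higher and 2 lower of 13 (camera adjusted p = 0.0170, adjusted p = 0.0524 with an estimated correlation), with BCL3 (30.3±2.4 against 2.66±0.34) and KLF4 (253±35 against 7.57±1.7). Plasma protein genes AFP (0.0477±0.017 against 10.7±0.58) and APOB (0.0492±0.024 against 2.63±0.57) were lower. MEG3 (1013±277 against 0.707±0.040), a maternally expressed noncoding RNA, was higher, as were TRIB3 (166±46 against 9.84±0.21) and DDIT3 (30.7±2.4 against 1.82±0.66). The largest rises outside these lists were ZNF208 (107±11 against 0, at least 1779-fold) and ZNF257 (65.4±2.8 against 0), and the largest falls STC1 (0 against 48.7±0.97, at least 1342-fold), a secreted glycoprotein, and MAGEB17 (0 against 51.4±4.7). Mitochondrial transcripts made 2.53±0.95 percent of counts against 6.48±1.06.

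RSeT naive cells differed from conventional cells in fewer genes (n = 2 and 2), 2459 higher and 2240 lower. All naive genes were higher (20 of 20 higher, camera adjusted p = 1.45e-42), but at lower levels than in the other media, with KLF17 (7.42±0.18 against 0), DPPA3 (70.5±0.47 against 0.175±0.13), DPPA5 (141±0.87 against 2.32±0.29) and ZNF729 (37.7±7.1 against 0.0998±0.019). In the conventional list, 13 of 20 were lower (camera adjusted p = 8.42e-08, adjusted p = 0.0537 with an estimated correlation), with FAT3 (5.23±0.54 against 76.7±3.2), DUSP6 (2.56±0.47 against 33.8±3.7), CYTL1 (0.510±0.23 against 3.98±0.18) and NLGN4X (40.4±4.7 against 313±6.7), a neuronal adhesion protein. NANOG (52.5±1.3 against 35.2±0.13) and SOX2 (237±13 against 352±0.90) were not called. Primitive streak genes were higher (13 higher and 1 lower of 18, camera adjusted p = 4.66e-08, adjusted p = 0.0537 with an estimated correlation), with TBXT (57.1±1.8 against 0.370±0.15, log2 fold change 7.27±0.97 SE, adjusted p = 7.34e-07), the T-box factor of the streak, MIXL1 (77.7±3.2 against 1.41±0.40) and HAND1 (39.04±0.72 against 0.0216±0.031). Endoderm factors HNF4A (6.30±0.58 against 0.113±0.16), GATA6 (17.1±0.70 against 0.561±0.059) and GATA4 (12.2±0.12 against 0.407±0.097) were higher too. Secreted plasma proteins gave 13 higher and 1 lower of 18 (camera adjusted p = 1.39e-06, adjusted p = 0.0528 with an estimated correlation), with APOA1 (15.97±2.6 against 0.696±0.24) and the fibrinogen chain FGA (14.9±1.8 against 0, at least 247-fold). WNT feedback genes SP5 (57.2±4.2 against 2.39±0.51) and LEF1 (5.04±0.22 against 0.472±0.24) were higher (7 of 15 higher, camera adjusted p = 7.47e-05, adjusted p = 0.130 with an estimated correlation, 8 and 0 adjusted over the list alone). So were Nodal genes NODAL (96.1±4.8 against 4.35±0.34) and GDF3 (187±15 against 4.78±0.096) (7 of 12 higher, camera adjusted p = 9.54e-04, adjusted p = 0.128 with an estimated correlation). Mesenchyme genes gave 10 higher and 2 lower of 15 (camera adjusted p = 2.64e-04, adjusted p = 0.146 with an estimated correlation), led by the proteoglycan LUM (34.5±3.4 against 0.321±0.026) and the fibrillar collagen COL3A1 (805±238 against 26.5±3.2). ERK genes EGR1 (2.44±0.48 against 92.96±4.6) and SPRY4 (15.99±0.015 against 117±2.6) were lower. Imprinted genes gave 6 higher and 1 lower of 18 (camera adjusted p = 7.58e-06), with PEG3 (42.6±1.5 against 0.167±0.13) and IGF2 (98.2±1.7 against 0.904±0.054).

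The naive cells of h2iL and t2iLGo (n = 3 and 3) differed in 154 genes higher and 194 lower in h2iL. No naive gene was called (0 of 20 called, camera adjusted p = 0.980), with KLF17 (49.04±5.2 and 44.8±0.36), DPPA3 (283±12 and 227±3.4) and DPPA5 (649±33 and 501±16) in h2iL and t2iLGo. Higher in h2iL were the cadherin CDH8 (30.2±2.7 against 5.18±0.50, log2 fold change 2.54±0.23 SE, adjusted p = 1.99e-08), the cartilage collagens COL2A1 (11.6±3.2 against 2.43±0.030) and COL11A1 (13.5±2.8 against 3.42±0.92), the matrix proteins THBS1 (193±29 against 61.00±3.3) and POSTN (13.8±3.2 against 4.81±0.80), and the immediate early gene EGR1 (5.36±2.7 against 0.209±0.069). Lower were ANXA1 (4.37±0.46 against 17.4±2.0, log2 fold change -1.99±0.38 SE, adjusted p = 7.38e-04), a phospholipid-binding protein, the phosphatase DUSP8 (3.33±0.31 against 15.96±1.5), the pluripotency-linked factor KLF2 (2.17±0.72 against 10.8±1.2), the scavenger receptor OLR1 (3.22±0.21 against 18.5±1.3) and LAMP3 (2.77±0.58 against 17.8±1.0). Stress genes TRIB3 (166±46 against 395±4.0) and ATF3 (27.6±1.8 against 58.4±2.2) were lower in h2iL. CCND1 (15.6±0.90 against 46.8±1.9), cyclin D1, was lower as well. Trophectoderm and amnion markers gave 3 of 14 lower (camera adjusted p = 0.0206, adjusted p = 0.189 with an estimated correlation, 0 and 5 adjusted over the list alone), with GATA3 (1.76±0.28 against 3.96±0.45) and KRT7 (0.413±0.12 against 1.29±0.24) lower. Both calls end when single libraries are left out (adjusted p up to 0.101 and 0.0936). The proliferation list gave 0 of 15 called (camera adjusted p = 1.04e-08, adjusted p = 0.189 with an estimated correlation). POU5F1 (888±32 and 985±24), NANOG (171±2.9 and 155±2.6) and SOX2 (183±12 and 149±3.3) were not called.

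RSeT naive cells against t2iLGo naive cells (n = 2 and 3) gave 5190 genes higher and 3270 lower, and with scaling by library totals 6303 and 2332. Naive genes were lower in RSeT (18 of 20 lower, camera adjusted p = 1.82e-13), with the naive surface marker SUSD2 (40.2±6.0 against 1111±9.0, log2 fold change -4.79±0.23 SE, adjusted p = 2.62e-16), ALPG (113±11 against 2269±17), a germ cell phosphatase, DNMT3L (85.2±3.0 against 1223±36) and KHDC1L (1.85±0.084 against 46.6±3.9). Every conventional gene was higher (20 of 20 higher, camera adjusted p = 5.56e-20), with THY1 (39.6±0.71 against 0.107±0.097), FZD7 (133±8.3 against 1.89±0.31) and PTPRZ1 (74.7±9.8 against 0.191±0.096). The same held for FGF and ERK genes (16 of 16 higher, camera adjusted p = 3.40e-09, adjusted p = 0.0647 with an estimated correlation), with SPRY4 (15.99±0.015 against 0.0590±0.024), ETV5 (11.6±0.41 against 0.524±0.14) and DUSP4 (5.09±0.68 against 0.222±0.11). TBXT (57.1±1.8 against 2.60±0.18), HAND1 (39.04±0.72 against 1.33±0.44), FOXA2 (3.68±0.20 against 0.154±0.16) and SOX17 (4.15±0.26 against 0.268±0.045) were higher, and so was PDGFRA (13.6±2.1 against 0.462±0.18). Within the LIF list TFCP2L1 (30.02±2.3 against 234±12) and KLF4 (65.4±1.7 against 260.4±5.1) were lower and SOCS3 (33.2±0.88 against 4.89±0.26) higher. WNT genes LEF1 (5.04±0.22 against 0.134±0.044) and SP5 (57.2±4.2 against 4.24±0.35) were higher (8 higher and 2 lower of 15, camera adjusted p = 0.00181, adjusted p = 0.293 with an estimated correlation). Basement membrane genes gave 9 higher and 2 lower of 20 (camera adjusted p = 2.92e-05, adjusted p = 0.183 with an estimated correlation), with P3H2 (33.1±3.5 against 0.117±0.064), a collagen prolyl hydroxylase, and COL4A6 (15.8±2.5 against 0.3498±0.30). IGF2 (98.2±1.7 against 2.71±0.52) was higher and MEG3 (83.05±9.4 against 844±57) lower. The stress genes TRIB3 (26.2±2.1 against 395±4.0) and HMOX1 (19.5±0.69 against 74.3±1.0), heme oxygenase, were lower. The top of the table held CER1 (35.6±3.7 against 0, at least 798-fold), a Nodal and BMP antagonist, and the bottom FAM151A (1.71±0.060 against 524±13).

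When t2iLGo naive cells became PrE (n = 3 and 3), 5665 genes rose and 4360 fell. Basement membrane genes rose (16 of 20 up, camera adjusted p = 1.05e-26), with the type IV collagen chain COL4A1 (6313±734 against 52.9±2.4, log2 fold change 6.90±0.10 SE, adjusted p = 1.82e-29), the nidogen NID2 (1884±199 against 4.29±1.0) and FN1 (21689±3869 against 153±2.4), fibronectin. In the extra-embryonic endoderm list, 18 rose and 1 fell of 24 (camera adjusted p = 4.83e-15), with PDGFRA (87.1±24 against 0.462±0.18, log2 fold change 7.55±0.44 SE, adjusted p = 2.76e-15), a receptor of primitive endoderm, and FLT1 (986±112 against 1.25±0.41). The endoderm factors GATA4 (141±27 against 3.32±0.45), GATA6 (126±26 against 1.92±0.25), SOX17 (10.2±1.2 against 0.268±0.045) and FOXA2 (2.36±0.77 against 0.154±0.16) rose, and so did CXCR4 (35.5±1.7 against 0.514±0.26), while HNF4A (6.06±1.7 against 21.4±1.9) and HHEX (2.50±0.083 against 8.24±0.44) fell. The whole naive list fell (20 of 20 down, camera adjusted p = 2.18e-25), with DPPA5 (0.503±0.33 against 501±16, log2 fold change -9.95±0.30 SE, adjusted p = 1.54e-20), DNMT3L (1.11±0.26 against 1223±36) and KLF17 (0.8005±0.38 against 44.8±0.36). Core factors fell (11 of 15 down, camera adjusted p = 7.38e-08, adjusted p = 0.177 with an estimated correlation), with NANOG (0.162±0.038 against 155±2.6), POU5F1 (1.62±0.10 against 985±24) and SOX2 (5.41±2.8 against 149±3.3). Mesoderm genes HAND1 (504±25 against 1.33±0.44) and FOXF1 (39.8±9.2 against 0.177±0.037) rose. Mesenchyme genes gave 13 up and 2 down of 15 (camera adjusted p = 7.29e-12), with COL6A3 (3798±812 against 3.69±0.20), LUM (73.4±18 against 0.425±0.27) and THY1 (18.6±1.7 against 0.107±0.097). The WNT antagonist DKK1 (200.3±42 against 0, at least 4496-fold) and the WNT effector LEF1 (249.9±6.5 against 0.134±0.044) rose (10 up and 2 down of 15, camera adjusted p = 2.25e-07, adjusted p = 0.0647 with an estimated correlation), as did ERK feedback genes DUSP6 (57.5±19 against 0.197±0.12) and SPRY4 (72.7±18 against 0.0590±0.024) (FGF and ERK targets: 14 of 16 up, camera adjusted p = 7.78e-11, adjusted p = 0.0537 with an estimated correlation). The Nodal co-receptor TDGF1 (1.24±0.51 against 309.5±14) fell. Markers of other lineages rose in part, CDX2 (19.96±1.6 against 1.10±0.40) and GATA2 (57.1±8.5 against 4.25±1.3) of the trophectoderm and amnion list (6 up and 5 down of 14, camera adjusted p = 0.545) and TEK (167±23 against 3.38±0.14) of the endothelial list. The imprinted gene MEST (2103±106 against 115±1.9) rose. MT1H (0.0650±0.082 against 220.5±11), a metallothionein of a gene family whose counts may mix, and TRIB3 (12.1±1.9 against 395±4.0) fell.

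In h2iL, PrE against naive cells (n = 3 and 3) gave 5369 genes higher and 4091 lower, and 4416 rises and 3507 falls were shared with t2iLGo, 10 genes being called in opposite directions. Basement membrane genes gave 19 of 20 up (camera adjusted p = 7.33e-28), with COL4A1 (6152±670.0 against 79.8±3.5, log2 fold change 6.27±0.10 SE, adjusted p = 1.18e-28), FN1 (18579.8±2635 against 228±6.8), NID2 (1614±125 against 3.80±0.33) and the collagen COL18A1 (2627±206 against 31.99±2.9). Of the extra-embryonic list, 21 rose and 1 fell of 24 (camera adjusted p = 3.91e-15), with FLT1 (827±101 against 1.25±0.41) and PDGFRA (60.9±26 against 0.287±0.091). GATA6 (123±12 against 0.826±0.34), GATA4 (151±52 against 1.90±0.39), FOXA2 (3.47±2.5 against 0.0497±0.059), CXCR4 (32.7±3.0 against 0.384±0.085) and SOX17 (10.6±1.8 against 0.180±0.057) rose while HNF4A (8.41±3.9 against 23.3±1.7) and HHEX (2.08±0.34 against 6.65±1.8) fell (shared endoderm: 7 up and 5 down of 12, camera adjusted p = 0.329). Naive genes fell (20 of 20 down, camera adjusted p = 1.89e-25), with DPPA5 (0.389±0.37 against 649±33, log2 fold change -10.67±0.31 SE, adjusted p = 6.55e-21), DPPA3 (7.07±3.7 against 283±12) and KLF17 (1.91±0.065 against 49.04±5.2), and of the core list NANOG (0.310±0.14 against 171±2.9), POU5F1 (2.50±1.3 against 888±32) and SOX2 (3.78±0.94 against 183±12) fell. DKK1 (142±19 against 0.0807±0.11) and LEF1 (255±25 against 0.117±0.11) rose, and so did HAND1 (488±27 against 0.684±0.16). Mesenchyme genes gave 13 of 15 up (camera adjusted p = 3.88e-11), with COL6A3 (4275±1144 against 5.78±0.90), LUM (61.5±15 against 0.0453±0.078) and COL5A1 (3552±399 against 83.9±9.9). Endothelial and blood genes TEK (141±16 against 2.21±0.44), CD34 (4.90±1.7 against 0.108±0.094) and TAL1 (1.10±0.32 against 0.0728±0.0046) rose (haematopoietic and endothelial: 8 of 10 up, camera adjusted p = 0.00749, adjusted p = 0.0774 with an estimated correlation). ERK genes DUSP6 (66.6±15 against 0.122±0.023) and SPRY4 (45.6±4.7 against 0.294±0.090) rose. LIX1 (211±38 against 0.0468±0.051, log2 fold change 11.95±0.38 SE, adjusted p = 1.89e-21) and the adrenergic receptor ADRA2A (72.4±6.1 against 0) were among the largest rises.

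The change from RSeT naive cells to RSeT PrE (n = 4 and 2) took 4231 genes up and 3732 down, and with scaling by library totals 3372 and 5034. Definitive endoderm genes rose (16 of 18 up, camera adjusted p = 2.25e-05, adjusted p = 0.206 with an estimated correlation), with CER1 (3645±736 against 35.6±3.7, log2 fold change 6.68±1.14 SE, adjusted p = 1.37e-05), GSC (231±101 against 1.46±0.22), LHX1 (183±12 against 0.647±0.040) and EOMES (375±110.3 against 8.76±0.42), a T-box factor of endoderm. Shared endoderm genes gave 11 of 12 up (camera adjusted p = 5.33e-05, adjusted p = 0.140 with an estimated correlation), with SOX17 (201±44 against 4.15±0.26, log2 fold change 5.59±0.61 SE, adjusted p = 4.20e-09), FOXA2 (116±51 against 3.68±0.20), HNF4A (214±75 against 6.30±0.58), GATA6 (669±451 against 17.1±0.70) and CXCR4 (619.9±173 against 1.60±0.12). In the extra-embryonic list, 19 of 24 rose (camera adjusted p = 1.07e-10), with BMP2 (272±159 against 15.3±1.0) and VIL1 (103±29 against 2.92±0.19), an actin-bundling protein of absorptive epithelia. Basement membrane genes COL4A1 (2676±132 against 225±0.61), HSPG2 (1839.8±269 against 64.9±2.4) and FN1 (7747±1264 against 740.5±35) rose (14 of 20 up, camera adjusted p = 4.32e-15). TBXT (9.16±2.3 against 57.1±1.8) fell while the primitive streak and mesoderm list gave 6 up and 4 down of 18 (camera adjusted p = 0.814), or 4 and 4 with scaling by library totals. Core factors POU5F1 (149±87 against 738±17), NANOG (12.9±2.9 against 52.5±1.3) and SOX2 (17.5±9.9 against 237±13) fell (11 of 15 down, camera adjusted p = 1.21e-06, adjusted p = 0.206 with an estimated correlation, 0 and 12 adjusted over the list alone), and naive genes gave 1 up and 17 down of 20 (camera adjusted p = 4.05e-16), with DPPA5 (1.17±0.36 against 141±0.87) falling and DPPA3 (53.8±34 against 70.5±0.47) not called over all 4 libraries but lower in the 2 marked New, taken alone (log2 fold change -1.55). Plasma protein genes AFP (0.221±0.089 against 15.7±2.7) and TF (0.185±0.075 against 8.34±0.95) fell (secreted plasma proteins: 5 up and 11 down of 18, camera adjusted p = 0.00363, adjusted p = 0.206 with an estimated correlation). The ERK gene DUSP4 (844±178 against 5.09±0.68) and the WNT gene LGR5 (167±96 against 2.35±0.18) rose. Stress genes HMOX1 (324±159 against 19.5±0.69) and CDKN1A (247±32 against 50.3±3.5) rose and cell cycle genes MCM2 (72.3±14 against 202±5.9) and BUB1 (90.8±13 against 200.2±6.4) fell (proliferation: 6 of 15 down, camera adjusted p = 2.87e-05, adjusted p = 0.206 with an estimated correlation), with 11 down by library totals. FOXQ1 (783±436 against 0.428±0.070, log2 fold change 10.83±0.77 SE, adjusted p = 7.28e-13), a forkhead factor, stood among the largest rises and MT1G (0.623±0.56 against 129±1.3) among the largest falls.

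**Figure D2:**
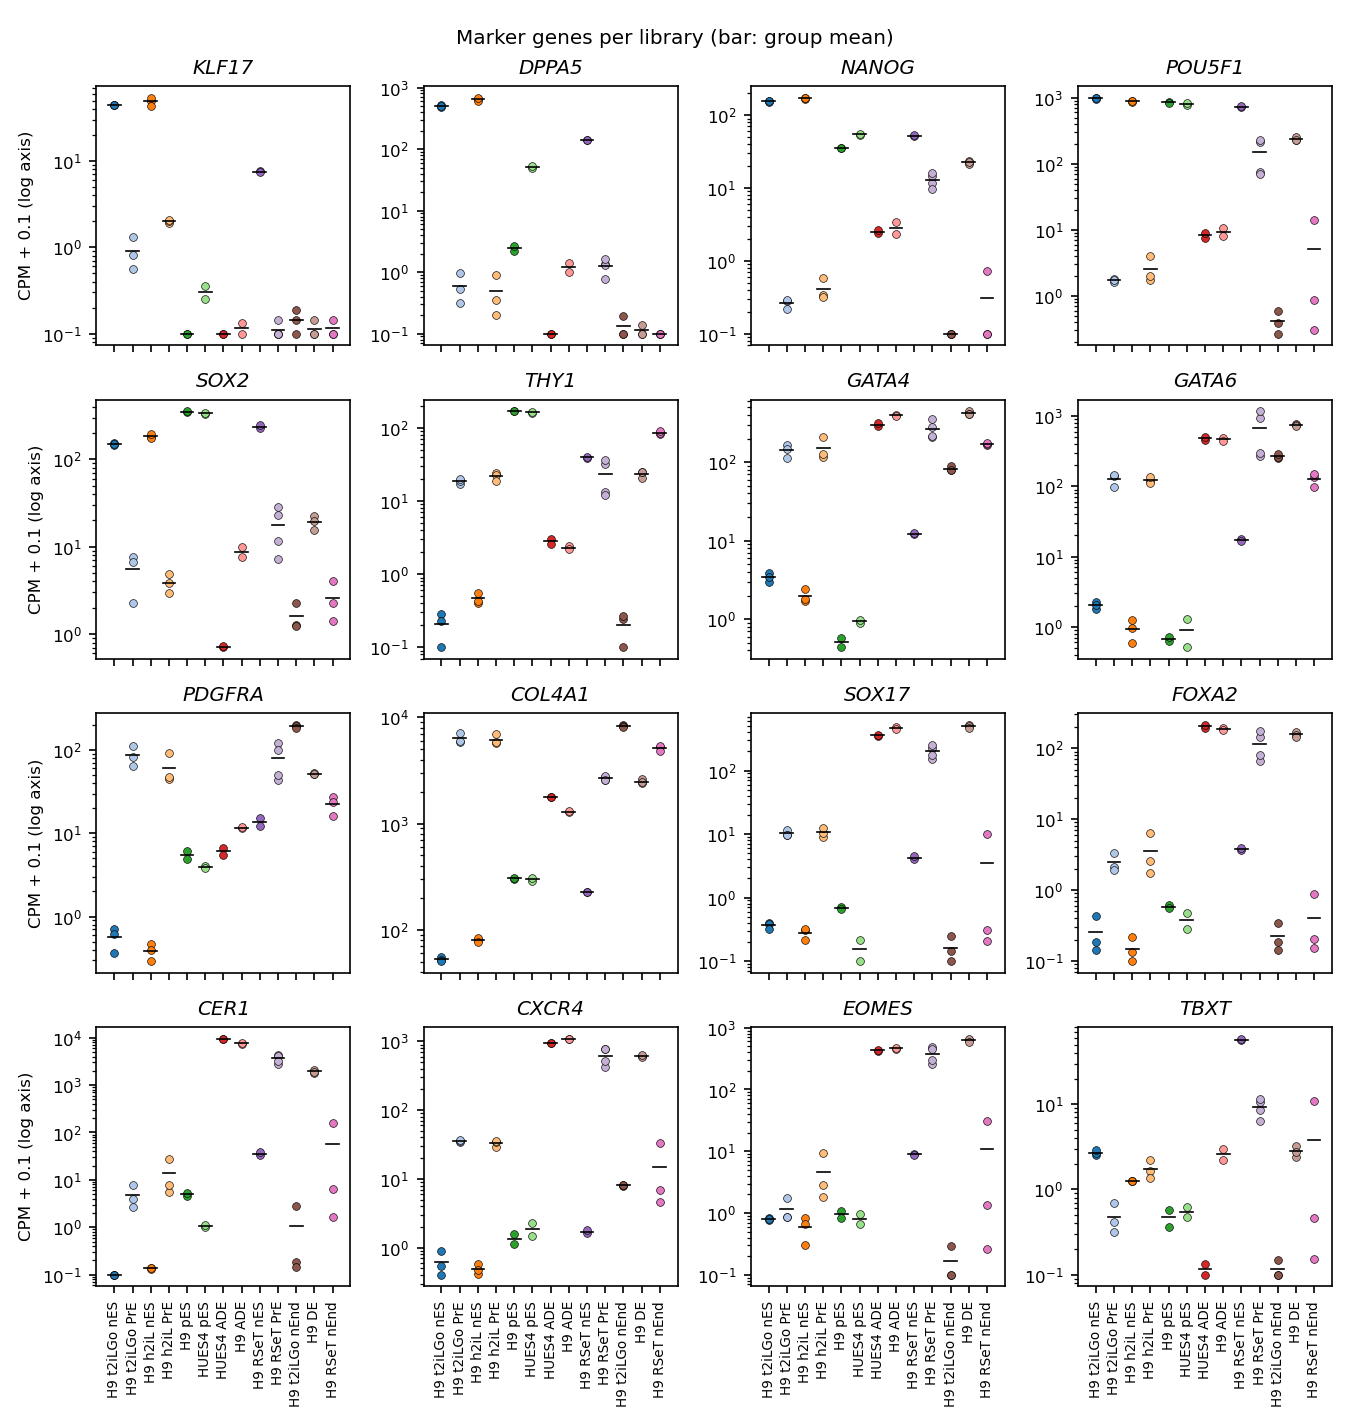
CPM of marker genes in each library by group, on a log axis with 0.1 CPM added. Each point is a library.

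Between t2iLGo nEnd and t2iLGo PrE (n = 3 and 3), 2137 genes were higher in nEnd and 3995 lower, and with scaling by library totals 1586 and 4795. Epithelial and endoderm markers SOX17 (0.0628±0.074 against 10.2±1.2, log2 fold change -7.30±0.99 SE, adjusted p = 4.72e-07), FOXA2 (0.124±0.10 against 2.36±0.77), HNF4A (0.166±0.065 against 6.06±1.7) and EPCAM (0.493±0.076 against 21.8±2.2) were lower, whereas KIT (587±45 against 5.54±1.3), a receptor tyrosine kinase, GATA6 (270.3±16 against 126±26) and PDGFRA (193±7.7 against 87.1±24) were higher. The last 2 calls end with scaling by library totals (log2 fold change 0.88 and 0.94) and without 1 library. COL4A1 (8289.9±166 against 6313±734) and GATA4 (82.9±5.9 against 141±27) were not called. Basement membrane genes split (2 higher and 3 lower of 20, camera adjusted p = 0.151), with SPARC (10631±876 against 3629±469.9), a matrix protein, and PLOD2 (1076±27 against 327±38) higher and COL18A1 (1131±83 against 2544±232) lower. Core pluripotency genes still present in PrE were lower, LIN28A (3.08±0.84 against 893±117), an RNA-binding protein, and DPPA4 (0.465±0.12 against 93.8±7.4). Endothelial genes gave 1 higher and 8 lower of 10 (camera adjusted p = 1.70e-06), with CDH5 (0.0930±0.087 against 26.7±1.4) and CD34 (0.0623±0.074 against 6.89±0.046) lower. FGF and ERK genes gave 9 of 16 lower (camera adjusted p = 1.32e-04, adjusted p = 0.240 with an estimated correlation), with SPRY1 (2.22±0.77 against 67.2±13) and DUSP6 (9.70±0.32 against 57.5±19) lower. The imprinted pair H19 (1311±174 against 165±39) and IGF2 (138±49 against 15.3±3.7) was higher and PHLDA2 (0.197±0.10 against 7.39±1.9), a growth-limiting imprinted gene, lower. FST (779±69.7 against 113±24), an Activin antagonist, and MEOX1 (134±12 against 1.95±0.58), a homeobox factor, were higher. Of the mesenchyme list DCN (56.1±2.3 against 0.898±0.16) was higher and THY1 (0.104±0.091 against 18.6±1.7) lower. RSPO3 (0.807±0.25 against 16.2±4.6), a WNT agonist, and CYP26A1 (1.05±0.27 against 110.4±14), which degrades retinoic acid, were lower. SLC6A20 (15.95±3.0 against 0.0759±0.041), an amino acid transporter, and the histone gene H2BC3 (83.4±1.9 against 0.0512±0.044) headed the genes higher in nEnd.

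RSeT nEnd against RSeT PrE (n = 3 and 4) gave 3556 genes higher and 4532 lower. With only the PrE libraries marked New, as all nEnd libraries are, 3050 were higher and 4059 lower, and with only the others 4617 and 4557. Definitive endoderm genes were lower (17 of 18 lower, camera adjusted p = 1.92e-08, adjusted p = 0.0809 with an estimated correlation), with CER1 (55.8±89.8 against 3645±736, log2 fold change -6.02±0.91 SE, adjusted p = 2.09e-06), GSC (0.786±1.0 against 231±101), EOMES (10.8±18 against 375±110.3) and CD177 (0.320±0.51 against 81.7±17). Shared endoderm genes gave 11 of 12 lower (camera adjusted p = 1.33e-10), with SOX17 (3.41±5.6 against 201±44, log2 fold change -5.82±0.52 SE, adjusted p = 6.38e-11), FOXA2 (0.308±0.40 against 116±51), HNF4A (0.459±0.66 against 214±75) and CXCR4 (14.9±16 against 619.9±173) lower. What CER1 and SOX17 remain in RSeT nEnd come mostly from replicate 3 (159 and 9.93 CPM, against 1.52 to 6.36 and 0.105 to 0.204 in the others). Mesenchyme genes were higher (12 higher and 1 lower of 15, camera adjusted p = 7.21e-10), with COL3A1 (21741±7889 against 926±294, log2 fold change 4.55±0.24 SE, adjusted p = 7.85e-16), COL6A3 (7317±1077 against 161±34), COL5A1 (9679.8±382 against 799±232) and DCN (184±113 against 15.5±7.3). NID2 (703±348 against 51.9±17) and PLOD2 (998±96 against 126±54) were higher and HSPG2 (367±28 against 1839.8±269) and P3H2 (19.7±26 against 581±132) lower. WNT genes NKD1 (643±83 against 37.3±19) and LEF1 (103±5.5 against 6.79±1.4) were higher and LGR5 (7.45±12 against 167±96) lower (5 higher and 2 lower of 15, camera adjusted p = 0.0230, adjusted p = 0.377 with an estimated correlation). Plasma protein genes APOA1 (1.65±1.9 against 129.7±94) and APOA2 (0.310±0.37 against 17.8±9.3) were lower, and so were VIL1 (0.171±0.21 against 103±29) and the ERK gene DUSP4 (41.2±7.4 against 844±178). Imprinted IGF2 (869.6±295 against 136±89.98), H19 (359±83 against 36.1±9.2) and MEG3 (157±130.1 against 23.6±7.5) were higher. MEOX1 (157±99 against 1.78±0.69) and THY1 (85.99±4.7 against 23.3±12) were higher. The neural factor PAX6 (0.157±0.16 against 8.37±2.7) was lower (1 higher and 6 lower of 12, camera adjusted p = 0.0403, adjusted p = 0.184 with an estimated correlation). The largest rises held SST (428±357 against 1.41±0.73), somatostatin, and CFI (180.0±47 against 0.127±0.14), a complement regulator. The naive list gave 16 of 20 lower (camera adjusted p = 9.96e-07).

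H9 ADE against H9 conventional cells (n = 2 and 2) showed 3787 genes up and 4263 down, or 3392 and 4728 with scaling by library totals. Definitive endoderm genes rose (18 of 18 up, camera adjusted p = 6.58e-12, adjusted p = 0.103 with an estimated correlation), with CER1 (7585±229.7 against 4.83±0.47, log2 fold change 10.61±1.40 SE, adjusted p = 3.10e-07), FGF17 (1471±16 against 0.777±0.18), LEFTY2 (8466±12 against 39.9±1.2), a Nodal antagonist, GSC (315±14 against 0.532±0.17) and EOMES (464±4.1 against 0.855±0.20). Shared endoderm factors gave 11 up and 1 down of 12 (camera adjusted p = 1.24e-10), with SOX17 (471±18 against 0.585±0.029, log2 fold change 9.64±0.80 SE, adjusted p = 2.70e-11), FOXA2 (189±10.3 against 0.486±0.047), GATA6 (468±32 against 0.561±0.059), GATA4 (396±9.98 against 0.407±0.097) and HNF4A (143±4.5 against 0.113±0.16), and CXCR4 (1086±4.5 against 1.24±0.32), the surface receptor used to sort definitive endoderm. HHEX (102±3.3 against 0.966±0.41), a homeobox factor of anterior endoderm, rose. Core factors fell (11 of 15 down, camera adjusted p = 5.38e-06, adjusted p = 0.208 with an estimated correlation), with POU5F1 (9.27±1.7 against 851±11) and SOX2 (8.60±1.6 against 352±0.90). Conventional genes PTPRZ1 (2.89±0.054 against 307±14), FGF2 (0.594±0.17 against 209±1.4) and THY1 (2.21±0.14 against 168±0.049) fell (3 up and 12 down of 20, camera adjusted p = 2.86e-05, adjusted p = 0.166 with an estimated correlation). HSPG2 (1352±9.2 against 222±0.27), COL4A6 (270.3±4.3 against 48.9±0.96) and FN1 (2032±41 against 434±2.3) rose and NID1 (13.1±1.3 against 70.3±1.9) fell (basement membrane: 9 up and 3 down of 20, camera adjusted p = 0.0112, adjusted p = 0.449 with an estimated correlation). The mesenchymal collagens COL3A1 (0.0987±0.043 against 26.5±3.2) and COL6A3 (0.3505±0.13 against 37.9±0.35) fell. The LIF receptor LIFR (152±3.4 against 27.4±2.5) rose and STAT3 (21.96±2.2 against 146±1.9) fell. DNMT3B (262±4.6 against 1874±10.5) fell. Cell cycle genes MKI67 (83.04±8.7 against 298±2.0) and TOP2A (135±0.99 against 463±13) fell (proliferation: 5 of 15 down, camera adjusted p = 2.48e-05, adjusted p = 0.208 with an estimated correlation). Mitochondrial transcripts made 2.57±0.437 percent of counts against 6.48±1.06, and of that list 11 of 13 fell (camera adjusted p = 0.00234, adjusted p = 0.523 with an estimated correlation). FOXQ1 (798±14 against 0.156±0.099) and TFF1 (37.5±2.7 against 0), a secreted peptide of the stomach, were among the largest rises and COL12A1 (0.103±0.098 against 219±3.0) among the largest falls. ZNF680 and ZNF253 are among 6 genes that stay under 0.2 CPM in H9 pES and H9 DE but have at least 2 CPM in H9 ADE. The labels do not say whether all H9 groups come from one stock of cells, so comparisons between H9 groups, the naive ones included, do not tell stock from state.

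HUES4 ADE against HUES4 conventional cells (n = 2 and 2) gave 5163 rises and 5707 falls, or 4428 and 6435 with scaling by library totals, and 2822 rises and 3079 falls were shared with H9 ADE, 142 genes being called in opposite directions. Definitive endoderm genes gave 17 of 18 up (camera adjusted p = 2.04e-08, adjusted p = 0.209 with an estimated correlation), with CER1 (9346±124 against 0.950±0.075, log2 fold change 13.26±1.58 SE, adjusted p = 3.91e-08), LEFTY2 (10452±526 against 14.7±2.1), GSC (510.1±15 against 0.112±0.10) and FGF17 (1726±101 against 1.84±0.40). SOX17 (358±16 against 0.0557±0.079), FOXA2 (203±13 against 0.280±0.13), GATA6 (484±35 against 0.802±0.56), HNF4A (107±0.27 against 0.0934±0.13) and CXCR4 (949.9±16 against 1.79±0.57) rose (shared endoderm: 11 up and 1 down of 12, camera adjusted p = 2.56e-07, adjusted p = 0.183 with an estimated correlation). SOX2 (0.613±0.012 against 335±3.8), POU5F1 (8.20±1.1 against 807±21) and FOXD3 (0.181±0.012 against 26.6±2.2) fell (core pluripotency: 12 of 15 down, camera adjusted p = 4.90e-07, adjusted p = 0.215 with an estimated correlation). Of the conventional list FGF2 (0.825±0.15 against 376±16) and THY1 (2.74±0.30 against 162±6.3) fell. HSPG2 (2611±129 against 109±10.4, log2 fold change 4.58±0.23 SE, adjusted p = 2.32e-16), perlecan, FN1 (6856±240.1 against 375±15) and P3H2 (560.2±6.9 against 65.00±1.4) rose and NID2 (0.141±0.093 against 14.1±0.76) fell (basement membrane: 11 up and 3 down of 20, camera adjusted p = 1.35e-05, adjusted p = 0.209 with an estimated correlation). BMP2 (369±18 against 3.80±0.038) and LGR5 (139.8±1.4 against 0.335±0.10) rose and CCND1 (13.8±0.29 against 199±1.3) fell. Stress genes TRIB3 (53.3±0.95 against 5.83±1.2) and GADD45A (143±4.8 against 19.1±1.1) rose, and replication genes MCM2 (64.5±3.7 against 246±18) and PCNA (76.01±0.89 against 282±23) fell. DUSP4 (1019±3.8 against 17.9±0.81) rose while FOS (2.41±0.31 against 31.4±1.4) fell, and FGF and ERK genes gave 7 up and 5 down of 16 (camera adjusted p = 0.260), or 4 and 7 with scaling by library totals. DPPA5 (0 against 50.3±3.0, at least 929-fold) and KRT7 (0 against 10.3±1.1) had no counts in HUES4 ADE.

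From H9 conventional cells to H9 DE (n = 3 and 2), 3888 genes rose and 4439 fell, and with scaling by library totals 2886 rose and 5883 fell. Definitive endoderm genes rose (17 up and 1 down of 18, camera adjusted p = 4.12e-08, adjusted p = 0.106 with an estimated correlation), with CER1 (1946±164 against 4.83±0.47, log2 fold change 8.65±1.29 SE, adjusted p = 2.05e-06), MIXL1 (1102±51 against 1.41±0.40), EOMES (627±33 against 0.855±0.20) and FGF17 (840.0±78 against 0.777±0.18). SOX17 (503±23 against 0.585±0.029, log2 fold change 9.74±0.79 SE, adjusted p = 1.61e-11), FOXA2 (157±12 against 0.486±0.047), HNF4A (235±19 against 0.113±0.16), GATA6 (752±26 against 0.561±0.059) and GATA4 (422±17 against 0.407±0.097) rose (shared endoderm: 11 of 12 up, camera adjusted p = 3.56e-10). APOA1 (1254±159.8 against 0.696±0.24, log2 fold change 10.82±0.95 SE, adjusted p = 8.33e-11), the main protein of high-density lipoprotein, and CUBN (14.5±0.46 against 0.1996±0.038), its endocytic receptor, rose. The extra-embryonic list gave 19 up and 2 down of 24 (camera adjusted p = 3.08e-09). POU5F1 (235±15 against 851±11) and SOX2 (18.98±3.4 against 352±0.90) fell and NANOG (22.4±1.2 against 35.2±0.13) was not called. WNT genes rose (13 of 15 up, camera adjusted p = 4.58e-09), with LGR5 (142±4.2 against 0.218±0.064), DKK1 (126±22 against 0.278±0.087) and SP5 (202±15 against 2.39±0.51). COL4A1 (2483±102 against 306±4.3), LAMA1 (479.8±48 against 102±0.42), a laminin chain, and FN1 (2824±231 against 434±2.3) rose and NID2 (2.10±0.29 against 14.7±0.53) fell (basement membrane: 8 up and 1 down of 20, camera adjusted p = 2.95e-07, adjusted p = 0.0835 with an estimated correlation). LIFR (488±26 against 27.4±2.5) and SOCS3 (125±7.2 against 22.6±0.38) rose (7 up and 2 down of 13, camera adjusted p = 0.00709). The ERK gene DUSP4 (429±18 against 8.74±1.2) and the imprinted CDKN1C (293±30.0 against 14.6±0.94) and IGF2 (29.7±2.7 against 0.904±0.054) rose. HMOX1 (554±51 against 19.3±0.40) and TBX3 (115±12 against 2.72±0.0088), of the hepatic and gut list (6 up and 2 down of 10, camera adjusted p = 0.220), rose. MKI67 (63.6±5.7 against 298±2.0) and TOP2A (129±11 against 463±13) fell (proliferation: 10 of 15 down, camera adjusted p = 1.53e-08, adjusted p = 0.0835 with an estimated correlation). TYW3 (0.0285±0.025 against 17.2±0.57) and ZNF93 (0.0129±0.022 against 11.3±0.78) were among the largest falls, and neither is lost in H9 ADE.

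Between t2iLGo PrE and H9 ADE (n = 3 and 2), 4959 genes were higher in PrE and 4631 lower, or 4373 and 5173 with scaling by library totals. Definitive endoderm genes were lower in PrE (1 higher and 16 lower of 18, camera adjusted p = 1.59e-09, adjusted p = 0.0866 with an estimated correlation), with CER1 (4.69±2.6 against 7585±229.7, log2 fold change -10.65±1.16 SE, adjusted p = 6.67e-09), FGF17 (0.419±0.27 against 1471±16), LEFTY1 (0.862±0.66 against 1234±8.9) and CD177 (0.175±0.036 against 88.02±6.9). SOX17 (10.2±1.2 against 471±18, log2 fold change -5.53±0.51 SE, adjusted p = 1.25e-10), FOXA2 (2.36±0.77 against 189±10.3), EPCAM (21.8±2.2 against 731±22) and KIT (5.54±1.3 against 253±7.5) were lower too (shared endoderm: 1 higher and 11 lower of 12, camera adjusted p = 2.25e-06, adjusted p = 0.0766 with an estimated correlation). PDGFRA (87.1±24 against 11.6±0.17, log2 fold change 2.91±0.35 SE, adjusted p = 3.40e-08), FLT1 (986±112 against 4.40±0.55), NID2 (1884±199 against 3.17±0.33) and BMP6 (39.4±8.2 against 0.305±0.24) were higher, and APOA1 (28.9±9.1 against 46.3±4.1) was not called. Basement membrane genes gave 13 higher and 3 lower of 20 (camera adjusted p = 1.59e-09, adjusted p = 0.0766 with an estimated correlation), with LAMC1 (1497±153 against 84.7±5.5) and NID1 (273±39.6 against 13.1±1.3) higher and P3H2 (12.6±1.8 against 329±8.7) lower. Mesenchyme genes were higher (14 higher and 1 lower of 15, camera adjusted p = 8.82e-14), with COL3A1 (8088±1403 against 0.0987±0.043, log2 fold change 16.30±0.60 SE, adjusted p = 1.66e-19) and COL6A3 (3798±812 against 0.3505±0.13). HAND1 (504±25 against 0.634±0.080), DKK1 (200.3±42 against 3.17±0.33), CCND1 (765±25 against 13.6±1.6) and BAMBI (533±45 against 16.6±1.1) were higher. So were IL6ST (989±75 against 66.1±1.8) and OSMR (29.6±5.9 against 2.70±0.40), a receptor subunit for oncostatin M. OTX2 (5.11±2.6 against 704±19) and ZIC2 (4.64±1.1 against 267±1.1) were lower (conventional pluripotency: 3 higher and 11 lower of 20, camera adjusted p = 0.0372, adjusted p = 0.419 with an estimated correlation). MEG3 (374±153 against 3.26±0.28), TEK (167±23 against 4.32±0.92), GATA2 (57.1±8.5 against 0.701±0.26) and CDX2 (19.96±1.6 against 0.237±0.34) were higher. DUSP4 (39.7±6.8 against 786±18) was lower. PEG3 (73.1±4.4 against 0, at least 1281-fold) and HOXA13 (74.9±17 against 0) had no counts in H9 ADE.

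t2iLGo nEnd against H9 DE (n = 3 and 3) gave 4474 genes higher and 5310 lower, or 3862 and 5964 with scaling by library totals. SOX17 (0.0628±0.074 against 503±23, log2 fold change -12.93±0.84 SE, adjusted p = 3.35e-14), HNF4A (0.166±0.065 against 235±19), EOMES (0.0644±0.11 against 627±33), MIXL1 (0.173±0.23 against 1102±51) and EPCAM (0.493±0.076 against 736±39) were lower in nEnd, and the definitive endoderm list gave 17 of 18 lower (camera adjusted p = 6.76e-09, adjusted p = 0.157 with an estimated correlation). APOA1 (3.05±0.58 against 1254±159.8) was lower and PDGFRA (193±7.7 against 51.9±0.89) higher. SPARC (10631±876 against 1214±33), NID2 (910.1±56 against 2.10±0.29) and PLOD2 (1076±27 against 68.2±3.9) were higher (basement membrane: 12 higher and 2 lower of 20, camera adjusted p = 1.92e-07, adjusted p = 0.153 with an estimated correlation). Collagens were among the most abundant differences, COL3A1 (30699±1895 against 10.2±1.1, log2 fold change 11.55±0.37 SE, adjusted p = 4.30e-21) and COL6A3 (8002±257 against 8.31±0.61), with DCN (56.1±2.3 against 0.0565±0.067) higher and THY1 (0.104±0.091 against 23.5±2.3) lower. The LIF co-receptor IL6ST (1843±122 against 75.2±5.9) was higher. Imprinted H19 (1311±174 against 0.0964±0.055), MEG3 (721±46 against 1.19±0.19) and PEG3 (22.5±3.0 against 0.0850±0.042) were higher and CDKN1C (0.497±0.30 against 293±30.0), a cell cycle inhibitor, lower (9 higher and 4 lower of 18, camera adjusted p = 0.0936). ERK genes DUSP4 (5.60±0.83 against 429±18) and DUSP6 (9.70±0.32 against 126±8.3) were lower (FGF and ERK targets: 14 of 16 lower, camera adjusted p = 7.52e-06, adjusted p = 0.184 with an estimated correlation). LGR5 (0.394±0.21 against 142±4.2), SP5 (1.71±0.16 against 202±15) and OTX2 (0.129±0.22 against 459±13) were lower and MEOX1 (134±12 against 0.101±0.027) was higher. Cell cycle genes MKI67 (153±3.6 against 63.6±5.7) and TOP2A (321±26 against 129±11) were higher (proliferation: 5 of 15 higher, camera adjusted p = 0.0497, adjusted p = 0.563 with an estimated correlation). Mitochondrial transcripts made 4.99±0.215 percent of counts against 2.66±0.162. CLEC1B (367±37 against 0, at least 8570.3-fold) and WNT2 (122±27 against 0) had no counts in H9 DE, and THBD (0 against 68.5±3.5), thrombomodulin, none in nEnd.

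RSeT nEnd against the same DE cells (n = 3 and 3) had 5030 genes higher and 4462 lower. Mesenchyme genes gave 13 higher and 1 lower of 15 (camera adjusted p = 8.49e-17), with COL3A1 (21741±7889 against 10.2±1.1, log2 fold change 11.06±0.37 SE, adjusted p = 1.65e-20), COL6A3 (7317±1077 against 8.31±0.61), LUM (553±299 against 6.78±1.1) and DCN (184±113 against 0.0565±0.067). Shared endoderm genes were lower (12 of 12 lower, camera adjusted p = 9.22e-11), with HNF4A (0.459±0.66 against 235±19), FOXA2 (0.308±0.40 against 157±12) and SOX17 (3.41±5.6 against 503±23). The definitive endoderm list gave 17 of 18 lower (camera adjusted p = 4.55e-08, adjusted p = 0.122 with an estimated correlation), with CD177 (0.320±0.51 against 123±1.3), GSC (0.786±1.0 against 171±9.5) and FGF17 (5.61±8.7 against 840.0±78). NID2 (703±348 against 2.10±0.29) and PLOD2 (998±96 against 68.2±3.9) were higher and COL4A6 (15.1±18 against 178±10.03) and P3H2 (19.7±26 against 201±3.0) lower. MEOX1 (157±99 against 0.101±0.027) was higher. LEF1 (103±5.5 against 3.02±0.37) and NKD1 (643±83 against 80.3±4.4) were higher and LGR5 (7.45±12 against 142±4.2) and SP5 (37.8±15 against 202±15) lower. Imprinted H19 (359±83 against 0.0964±0.055), MEG3 (157±130.1 against 1.19±0.19), PEG3 (9.11±0.92 against 0.0850±0.042) and IGF2 (869.6±295 against 29.7±2.7) were higher (8 higher and 5 lower of 18, camera adjusted p = 0.0309, adjusted p = 0.188 with an estimated correlation). THY1 (85.99±4.7 against 23.5±2.3) was higher. CFI (180.0±47 against 0, at least 4205-fold) and WNT2 (81.3±56 against 0) had no counts in H9 DE, and GABRA4 (0 against 12.04±1.4) and RGS8 (0 against 21.4±0.46) none in nEnd.

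**Figure D3:**
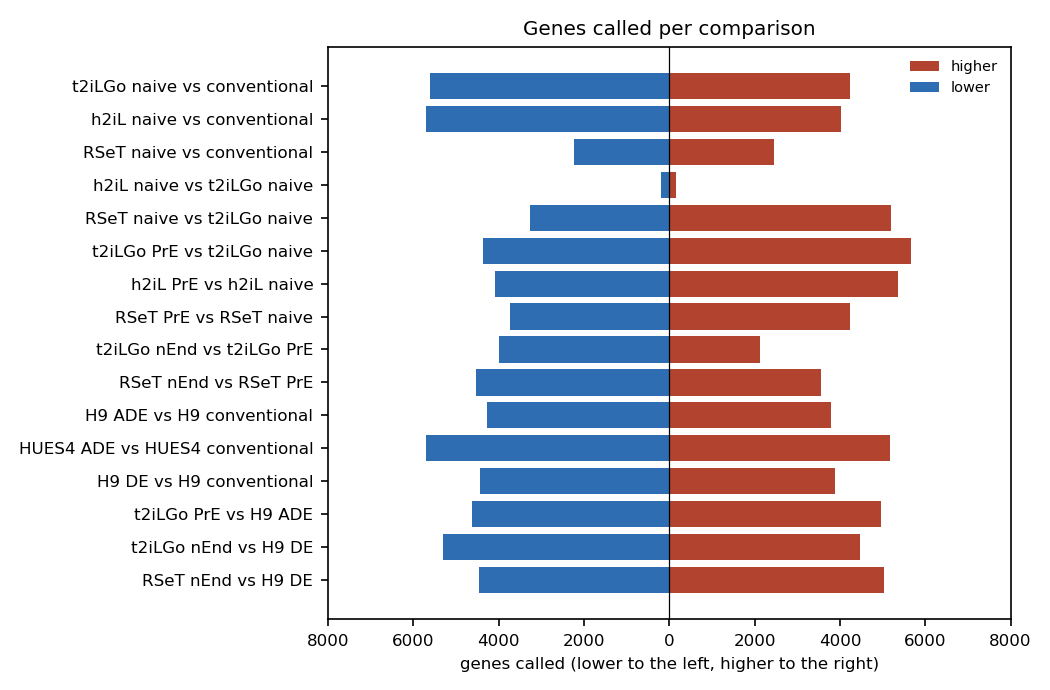
Genes called higher and lower in each comparison of 2 groups. The first group named is compared with the second.

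Whether the medium changes the PrE response was asked of h2iL against t2iLGo first, where the log2 change was higher for 215 genes and lower for 136 in h2iL. Stress and p53 genes gave 3 of 15 higher (camera adjusted p = 0.00166, adjusted p = 0.194 with an estimated correlation), definitive endoderm genes 2 of 18 higher (camera adjusted p = 0.0624, 3 and 0 adjusted over the list alone) and FGF and ERK genes 1 of 16 lower (camera adjusted p = 0.00402, adjusted p = 0.496 with an estimated correlation, 0 and 2 adjusted over the list alone).

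RSeT and t2iLGo differed far more in their PrE response, 3897 genes higher and 4481 lower in RSeT, or 3235 and 5487 with scaling by library totals and 4339 and 4171 with no filter. The change of definitive endoderm genes was higher in RSeT (11 higher and 2 lower of 18, camera adjusted p = 0.0156, adjusted p = 0.509 with an estimated correlation, 12 and 2 adjusted over the list alone), and shared endoderm genes gave 6 of 12 higher (camera adjusted p = 0.0194, adjusted p = 0.392 with an estimated correlation, 6 and 1 adjusted over the list alone). That of mesenchyme genes was lower (2 higher and 11 lower of 15, camera adjusted p = 2.79e-10), and so was that of basement membrane genes (2 higher and 12 lower of 20, camera adjusted p = 2.82e-10, adjusted p = 0.0506 with an estimated correlation), and of FGF and ERK genes (1 higher and 10 lower of 16, camera adjusted p = 9.79e-05, adjusted p = 0.267 with an estimated correlation). Naive genes, most of which start lower in RSeT, gave 15 higher and 4 lower of 20 (camera adjusted p = 2.13e-05).

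RSeT and t2iLGo also differed in nEnd against PrE, 4373 genes higher and 3097 lower in RSeT (4987 and 2637 by library totals). Medium and the mark New, on RSeT only, are not told apart. Mesenchyme genes gave 10 higher and 2 lower of 15 (camera adjusted p = 1.14e-06, adjusted p = 0.155 with an estimated correlation), WNT genes 9 higher and 1 lower of 15 (camera adjusted p = 1.09e-04, adjusted p = 0.291 with an estimated correlation) and shared endoderm genes 8 of 12 lower (camera adjusted p = 1.14e-06, adjusted p = 0.155 with an estimated correlation).

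In HUES4 against H9, whose conventional cells also differ in the letters DEF and MEF, the ADE change was higher for 1913 genes and lower for 2179. Naive genes gave 9 of 20 lower (camera adjusted p = 0.0196, adjusted p = 0.488 with an estimated correlation, 1 and 9 adjusted over the list alone) and basement membrane genes 5 higher and 1 lower of 20 (camera adjusted p = 0.00130, adjusted p = 0.721 with an estimated correlation, 7 and 1 adjusted over the list alone).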

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

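The results here are those where 2 groups respond differently by a test of the difference itself, and the tests of explanations for the patterns, other than the splits of samples, were chosen only after those patterns were seen. Among the 4 RSeT PrE libraries, 54 measures and gene values were examined for a library standing apart, and 0 passed the limit, where chance passes about 1 in 20. Such a limit cannot show a split into 2 pairs, which these libraries have.

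The PrE response differs between h2iL and t2iLGo in 351 genes. RASGRP1 (log2 difference 3.54±0.71 SE) and TMEM52B (3.11±0.47) had larger log2 rises in h2iL, both from lower naive levels, TMEM52B ending at 30.6±4.8 CPM in h2iL and 36.5±6.0 in t2iLGo. LAMP3 (3.15±0.52), a dendritic cell membrane protein, went down in t2iLGo (2.39±1.0 against 17.8±1.0 CPM) and not in h2iL (3.30±2.3 against 2.77±0.58). LEFTY1, a Nodal antagonist, went down less in h2iL (2.93±0.71). APOA1 ended at 32.1±18 CPM in h2iL PrE and 28.9±9.1 in t2iLGo PrE, from 0.0123±0.021 and 1.97±2.4, the latter with 4.79 in replicate 1 and 0.521 and 0.607 in the others. EGR1 (-3.63±0.59), POSTN (-2.71±0.35), PPP2R2B (-2.58±0.59) and NAP1L3 (-2.32±0.66) had smaller log2 rises in h2iL. CDH8 (-3.37±0.32) went up in t2iLGo (28.4±6.7 against 5.18±0.50 CPM) and down in h2iL (15.99±1.8 against 30.2±2.7). For all 5 the h2iL naive cells already stood higher in mean CPM. A fit of these groups alone called 716 genes, the highest of 99 other splits 434 and 15 of them any. If these libraries are separate cultures, chance can be excluded at a share under 0.05.

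RSeT and t2iLGo differ in the PrE response of 8378 genes. SEZ6 (10.53±0.81) and IRX6 (10.44±1.1) went up in RSeT and not in t2iLGo, SEZ6 to 179±38 CPM in RSeT PrE. NLRP9 (10.70±0.79) went up in RSeT (3.10±2.3 against 0.180±0.086 CPM) and down in t2iLGo (0.187±0.071 against 19.5±0.32). TEX101 (22.4±14 CPM in RSeT PrE, 0 in t2iLGo PrE) and the lung and thyroid factor NKX2-1 (13.1±6.9 against 0.136±0.071) went up in RSeT. LIX1 (-11.64±0.54) went up in t2iLGo, with 223±17 CPM in t2iLGo PrE and 2.76±1.4 in RSeT PrE. The zinc transporter SLC39A2 (58.0±1.9 CPM) and the peptide hormone CALCB (17.1±1.9) went from no counts in t2iLGo nES to these levels in t2iLGo PrE, with 1.44±0.44 and 0.370±0.035 in RSeT PrE. CXCL5 and VAT1L had no counts in t2iLGo nES and 20.4±1.2 and 49.4±0.73 CPM in RSeT nES.

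The step from PrE to nEnd differs between RSeT and t2iLGo in 7470 genes, or in 6717 with only the RSeT PrE columns marked New, as all RSeT nEnd columns are, and 8352 with only the others. THY1 went up in RSeT and down in t2iLGo (9.30±0.54). THBD reached 181±111 CPM in RSeT nEnd and was without counts in t2iLGo nEnd. ADA2 (42.4±6.4 CPM in RSeT PrE), SHISA2 (11.3±4.1 in t2iLGo PrE) and CALCB (17.1±1.9 in t2iLGo PrE) were lost in t2iLGo nEnd. KIT (-11.34±0.29), the amino acid transporter SLC6A20 (-12.98±0.47) and the sugar transporter SLC5A9 (-13.36±0.44) went down in RSeT and up in t2iLGo. RGS8 (25.5±17 CPM) and H2BC3 (168±195) of RSeT PrE were without counts in RSeT nEnd. H2BC3 had 309 and 361 CPM in the unmarked RSeT PrE libraries and none in those marked New. A fit of these groups alone called 6458 genes, the highest of 99 other splits 4693 and 11 of them any. Chance can be excluded at a share under 0.05 if all these libraries, the 4 of RSeT PrE included, are separate cultures. The labels do not say this.

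HUES4 and H9 differ in the ADE response of 4092 genes. The conventional columns carry MEF in H9 and DEF in HUES4, so line and culture are not told apart. COL12A1 (4.59±1.6) fell less in HUES4, where it began lower. TM4SF18 (4.92±0.70) went down in H9 (1.46±0.43 against 29.1±2.5 CPM) and stayed low in HUES4 (1.30±0.13 against 0.857±0.15). CUZD1 (20.4±4.4 CPM) and FEZF1 (13.5±0.38) of H9 pES fell to near 0 in H9 ADE, and the noncoding RNA PANCR rose to 14.5±1.2 CPM in H9 ADE and 11.4±0.65 in HUES4 ADE. PNPLA4 (12.4±0.23 CPM in HUES4 ADE), ZNF680 (24.5±2.3 in HUES4 pES) and ZNF253 (17.7±0.80 in HUES4 pES) were near 0 in H9 pES. CHCHD2, a mitochondrial protein, had 109±2.4 CPM in H9 pES and 4.17±0.068 in HUES4 pES, and DPPA5 50.3±3.0 in HUES4 pES.

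Mesenchyme genes rose in PrE of t2iLGo and h2iL. Scaling moved by a few abundant genes, which would move all genes alike, is excluded as the whole cause. The lower quartile of the list is a log2 fold change of 2.84 in t2iLGo and 1.99 in h2iL, against a median over all genes of 0.11 and 0.07 (2.80, 1.95, 0.07 and 0.03 with library totals). Mixed-in fibroblasts would bring DCN (0.898 CPM in t2iLGo PrE), but this test cannot tell without a fibroblast library. In RSeT PrE 7 of 15 rose and 0 fell (6 and 2 with library totals), so the rise is partly shared. The cause stays open.

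RSeT PrE correlates with H9 DE more closely than t2iLGo PrE does. An exchange of some libraries is excluded, since of the genes missing in every H9 DE library that all groups but these 2 hold at 2 CPM or more, 11 of 11 have at least 2 CPM in every RSeT PrE library. Exchanging whole groups would keep the pattern, t2iLGo PrE reaching at most r = 0.919 with RSeT PrE. An effect of the marked RSeT PrE set is excluded too. Either set correlates with H9 DE at 0.961 or more, against at most 0.905 for t2iLGo PrE. The state of the RSeT cells before differentiation could underlie the pattern and was not tested. The labels do not say which medium each group had, the H9 DE columns carry the letters RACL, and neither was tested.

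Other splits of the samples were made for 7 comparisons of 2 groups, and in each only 1 split, the real one, called any gene, with 0 the highest other. With 10 splits each the splits are too few for a share under 0.05 in h2iL against t2iLGo naive cells (478 genes), PrE against naive cells in t2iLGo (8307) and h2iL (8003), t2iLGo nEnd against PrE (4897), and t2iLGo (8093) and RSeT (7420) nEnd against DE. For RSeT nEnd against PrE, with 35 splits and 6005 genes, chance can be excluded if all libraries are separate cultures. If the 4 of PrE come from 2 there are 10 splits, too few.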

How the results depend on the processing

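Counts of called genes stayed within 1.5 times the main value, with RLE scaling (ratios 0.99 to 1.01), DESeq2 (0.93 to 1.43), the filter of 1 CPM (0.81 to 0.98) and the RSeT PrE libraries summed by number (0.99 to 1.02) or set (0.97 to 0.99), and so with the settings chosen after seeing the data, library totals alone (0.93 to 1.06) and the marked (0.88 to 0.97) or unmarked (1.04 to 1.13) RSeT PrE set alone. Without a minimum fold, which admits more genes by construction, the counts are 14773 for h2iL and 8451 for RSeT naive against conventional cells, 1830 for h2iL and 13544 for RSeT against t2iLGo naive cells, 15214, 14858 and 13227 for PrE in t2iLGo, h2iL and RSeT, 11469 and 14001 for nEnd against PrE in t2iLGo and RSeT, 12519 for H9 ADE, 13279 for H9 DE, 14568 for t2iLGo PrE against ADE, 14987 and 14927 for t2iLGo and RSeT nEnd against DE, 980 for h2iL minus t2iLGo in PrE response, 11351 for RSeT minus t2iLGo in nEnd against PrE, and 6472 for HUES4 minus H9 in ADE response. At an adjusted p under 0.01, stricter by construction, h2iL against t2iLGo naive cells gives 174 genes and the h2iL minus t2iLGo response 162. The latter gives 548 with no filter and 716 with only the groups compared, and the cause was not tested. Leaving out 1 library at a time, these 2 results ran from 212 to 282 and from 229 to 311, fewer samples giving fewer calls, and a lone sample left in a group is assumed to vary like the other groups. Replicate numbers do not pair the samples (deviations of same-numbered libraries do not correlate throughout), and a replicate block moved the 16 counts by ratios of 0.78 to 1 (273 genes for the h2iL minus t2iLGo response, 322 for h2iL against t2iLGo naive cells). It was not run, because the labels do not tie the numbers of the RSeT PrE columns to samples, for PrE against naive cells in RSeT, nEnd against PrE in RSeT and the 2 differences built on them. The larger of the 2 directions also changes for RSeT naive against conventional cells (4146 higher, 4305 lower), RSeT PrE (6590, 6637) and H9 DE (6651, 6628) without a minimum fold, for h2iL against t2iLGo naive cells (168, 166) with the filter of 1 CPM, and for t2iLGo PrE against ADE (5126, 5277) and RSeT minus t2iLGo in PrE response (4339, 4171) with no filter. Library totals in place of TMM shift the median log2 fold change from 0.06 to 0.34 for RSeT against t2iLGo naive cells, from 0.01 to -0.25 for RSeT PrE, from -0.01 to -0.31 for H9 DE, from -0.04 to -0.27 and from -0.05 to -0.24 for t2iLGo and h2iL naive against conventional cells, from -0.05 to -0.26 for t2iLGo nEnd against PrE, from -0.03 to -0.15 for H9 ADE, from 0 to -0.17 for HUES4 ADE, from 0.08 to -0.05 for t2iLGo PrE against ADE, from -0.02 to -0.20 for t2iLGo nEnd against DE, and from -0.11 to -0.34 and from 0.08 to 0.24 for RSeT minus t2iLGo in PrE response and in nEnd against PrE. Of 470 values of named genes under 6940 alternatives in all, 0 changed direction, 13 lost the call and 8 gained it. Across lists, an estimated correlation ended 164 calls and left 296 results alike, fry on balance gave 129 more calls and 5 fewer, and fry in either direction 226 more and 2 fewer. Depth limits genes below about 0.2 CPM, where a group holds only a few counts.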

Other observations

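Of the 4 RSeT PrE columns 2 carry the mark New. The genes and lists given here were chosen after their values were seen, and the pairs were not tested against each other. Both marked libraries lie below both unmarked for 9 of 12 shared endoderm (1 above) and 12 of 18 definitive endoderm genes (4 above). So they do for 10 of 18 plasma protein and 10 of 15 proliferation genes (0 above), so this is not particular to endoderm. They lie above for 11 of 15 core pluripotency genes (1 below), 10 of 20 basement membrane genes (2 below) and 11 of 24 extra-embryonic endoderm genes (5 below). Among those below are GATA6 at 272 and 301 CPM against 933 and 1167, APOA1 at 54.6 and 47.5 against 180.1 and 237, and FOXA2 at 67.0 and 80.2 against 143 and 173. Among those above are POU5F1 (217 and 232 CPM against 75.4 and 70.9), SOX2 (22.7 and 28.7 against 11.6 and 7.18) and, of the conventional list (12 of 20 above, 6 below), THY1 (31.8 and 35.96 against 13.2 and 12.1). COL4A1 stood alike in all 4 (2825 and 2582 against 2550 and 2748).

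RSeT nEnd replicate 3 is highest for 15 of 15 core pluripotency, 17 of 18 streak and mesoderm and 16 of 18 definitive endoderm genes. So it is for 17 of 20 conventional pluripotency, 14 of 16 FGF and ERK and 9 of 12 shared endoderm genes. This is not particular to endoderm. It is highest for 10 of 24 extra-embryonic genes, lowest for 13. It is lowest for 11 of 15 mesenchyme and 13 of 15 proliferation genes, the latter all highest in replicate 2. It held EOMES at 31.2 CPM against 0.157 and 1.22, TBXT at 10.7 against 0.0524 and 0.356, and POU5F1 at 14.01 against 0.209 and 0.764. GATA4 (173 CPM against 166 and 170.4) and COL4A1 (4824 against 5211 and 5334) were alike in the 3 libraries, and GATA6 (98.5 CPM against 138 and 150) and PDGFRA (15.9 against 27.3 and 23.4) were lowest in replicate 3. In h2iL PrE, replicate 3 stood higher than replicates 1 and 2 for CER1 (28.1 CPM against 5.52 and 7.64), EOMES (9.14 against 1.70 and 2.77), FOXA2 (6.31 against 1.67 and 2.45) and PDGFRA (90.8 against 44.9 and 46.9).

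The genes missing in a group were chosen after their values were seen, and so were the tests of why. In H9 DE, 11 genes stay under 0.2 CPM that have at least 2 CPM in every library of the other 12 groups. They are CRYZ and TYW3, neighbours on chr1:74705482-74733408 and chr1:74733152-74766678, and on chromosome 19 the zinc finger genes ZNF559, ZNF93, ZNF90, ZNF486, ZNF100, ZNF681, ZFP82, ZNF585A and the pseudogene ZNF542P. Chromosome 19 holds 9 of the 11, against 709 of the 9650 genes that could have been missing (Fisher's exact test, two-sided p = 2.86e-09). Another 6 genes, ZNF680, ZNF253, ZNF737, ZNF626, ZNF493 and PNPLA4, are missing in H9 pES and H9 DE alone. In t2iLGo nEnd the missing genes are EVC2, CDCA7L, ACSS3, ADA2, KLF8 and SLC7A3, and in HUES4 ADE CHCHD2.

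Too little depth in H9 DE is excluded, since H9 pES, the group with the shallowest library, has 0 such genes. Why H9 DE lacks these genes stays open, and no biological explanation was tested.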
